A study of Mus musculus with 12 samples.

How the data were processed

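RNA was prepared from MB114 cells at 1, 5, 15 and 25 h on Matrigel, with 3 biological replicates per time, per the labels. The cells had been split 24 h before they were placed on the gel, and RNA was extracted with commercial kits and phenol-chloroform; 6 µg of total RNA per sample was turned into biotinylated cRNA and hybridised, per the labels' protocols. The deposited values are intensities on a linear scale, 1 per probe set and array, made with MAS5, per the submitters' processing notes; its version, background settings and detection calls are not given in the sources used here. The values themselves show the scaling that the authors applied: after 2% of the values was trimmed from each end, the mean was 500.1 to 500.2 on each array, while the medians ran from 154 to 209. No further normalization was applied here, since the deposited intensities were already scaled. Each sample was assigned to its time and number by its title, and 0 columns of other samples were left unused.

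The table held 22690 probe sets, of which 64 were control probe sets and were kept out of the tests, and 1 probe set with 2 empty values was dropped. GEO's platform annotation gave 1 gene symbol for 20380 probe sets, several for 691 and none for 1555. Matching 20364 of them by Entrez ID to a RefSeq gene table changed 0 symbols. Gene names therefore rest on annotation that can be old, and no coordinates are given because no genome build was used. Signals were log2-transformed. A probe set was kept when its signal reached the median of all signals (183.1) on at least 3 of the 12 arrays, which left 11652 probe sets with a single symbol, and the one with the highest mean log2 signal stood for its gene, leaving 7379 genes. None of the named calls was opposed by a call of the gene's other probe sets above the filter, but some were not shared: by 0 of the others for Mcm2, Lif, Lamc1 and Col3a1 at 15 h and Cdkn1a and Prrx1 at 25 h against 1 h, Cdkn1a and Col6a2 for 15 against 5 h, and Asns and Clu for 25 against 15 h; by a part of them for Hmgcs1 and Flt1 at 5 h, Kcnip1 and Prrx1 at 15 h and Flt1, Txnrd1 and Csf1r at 25 h, and Mcm3 and Prrx1 for 15 against 5 h.

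Time points were compared with limma 3.58.1 in R 4.3.3: a linear model with 1 mean per time was fitted to all 12 arrays (8 residual degrees of freedom), followed by eBayes with an intensity trend, and p-values were adjusted by Benjamini-Hochberg over the 7379 genes. An adjusted p under 0.05 was called a change. All tests are 2-sided. The comparisons were 5, 15 and 25 h against 1 h, 15 against 5 h and 25 against 15 h, with a moderated F test over the 4 times. The 3 comparisons against 1 h share their 1 h arrays, so no overlap or correlation between them is given. For 32 gene lists, 637 genes in all, members were counted as higher, lower or not past the test, over all genes and adjusted over the list alone. The 26 lists with at least 5 tested genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over lists, with an estimated correlation as the alternative. The lists, the tests, the filter and the rule for named genes were fixed before the data were examined. That rule took the 10 largest rises and falls against 1 h (5 each way for the other comparisons) among called genes whose 3 and 3 samples did not overlap and whose higher mean reached the 60th percentile of signals (304.7), up to 4 members per list with the smallest p, and Mfap5 and Lum. The text names part of these genes, a choice made for length after their values and lost calls were seen; counts of lost calls among the largest changes cover all of them.

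The lists covered immediate early genes, SRF and YAP targets, G1/S and DNA replication, G2/M and mitosis, ribosome biogenesis, the lysosome, the unfolded protein, amino acid, heat shock, interferon, oxidative (NRF2), inflammatory, hypoxic, p53 and TGF-beta responses, cholesterol biosynthesis, tip cells, the Notch pathway, microfibrils, basement membrane, collagens, integrins, matrix proteases and endothelial identity. Further lists held markers of fibroblasts, pericytes, leukocytes, epithelium, astrocytes, neurons, lymphatic endothelium and parietal endoderm, the tissue type behind the gel. Whether the markers of a list passed the brightness filter as often as all 12393 named genes was tested with 2-sided Fisher's exact tests, adjusted over the 32 lists.

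The ratio of 3' to 5' control probe sets, a sign of RNA integrity, ran from 0.751 to 0.876 for Gapdh and from 1.01 to 1.15 for beta-actin, with no difference between times in permutation tests of 100000 resamples (p = 0.26 and 0.279, adjusted over 5 measures 0.465 for both). Median signals differed between times with permutation p = 0.0258 (adjusted p = 0.129). Hybridisation spike-ins were 2.18-fold higher on the 4 arrays numbered 1 than on the others (permutation p = 0.00537, adjusted p = 0.0134), and the 18S rRNA 3' control was 10.0-fold higher (permutation p = 0.00053, adjusted p = 0.00265), which is why fits without these arrays were added. No 2 arrays shared more than 65 identical values. Equal replicate numbers, taken from the sample titles, paired the samples: deviations from the time means correlated between 0.328 and 0.758 across genes in all 18 pairs with equal numbers, and between -0.59 and 0.198 in pairs with different numbers.

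The steps were tested on simulated data with the real genes and spreads, 200 genes changed per comparison. Over the 5 comparisons, 40.3% to 53.7% of 2-fold changes, 86.4% to 92.4% of 4-fold changes and at most 11.9% of 1.5-fold changes were recovered. False calls made up 3.8% to 8% of calls, and with no change the F test called 0 genes. These rates do not calibrate the real arrays, where up to 2705 genes were called and equal numbers shared deviations. Alternatives tried were quantile normalization, centring on the median, no filter, a stricter filter at the 60th percentile, an offset of 44.9 (the 25th percentile) before log2, averaging a gene's probe sets, testing every probe set, no intensity trend, the 6 arrays of a comparison alone, the replicate number as a block, leaving out each array and an estimated correlation. Fits without arrays numbered 1 or 3, combinations with the block and the fit of Lum came after the data were seen.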

Results

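MB114 cells, a mouse line of microvascular endothelial origin, were sampled at 4 times after transfer to Matrigel, a gel of basement membrane proteins from a mouse tumour on which endothelial cells align into cords and capillary-like networks. RNA was collected after 1, 5, 15 and 25 h, with 3 samples at each time that the labels name biological replicates 1 to 3. Each of the 12 samples was hybridised to 1 Affymetrix mouse array of 22690 probe sets. The series asks which transcripts change while these cells form networks in vitro, and no culture off the gel was analysed here, so the 1 h samples served as the starting point. The values are MAS5 signals, intensities on a linear scale that summarise the probes of a transcript, and the deposited values had been brought to nearly the same trimmed mean on every array (500.1 to 500.2). Signals ran from 0.1 to 37764.1, with a median of 154 to 209 per array, and 7379 genes were bright enough to test. Arrays have no read depth, and their number, 3 at each time, limits the precision: an exact permutation test of 3 against 3 samples cannot give a p below 0.1, so genes were tested with limma, which shares the spread over all 12 arrays.

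Across the tested genes, arrays of the same time correlated with r between 0.904 and 0.959, and 1 h arrays correlated with 25 h arrays with r between 0.710 and 0.819. These correlations are across genes, which are not independent replicates. Each array's deviation from its time mean was closest to that of another array with its own replicate number in 12 of 12 cases, so the numbers pair the samples, and results whose call changed with the replicate number as a block, or whose count moved by over 1.5 times, are given with both values. Gene lists were tested with limma's camera; of 46 list results called over the 5 comparisons, 34 kept their call in 25 alternatives other than an estimated correlation, and the adjusted p ranges of the other 12 are given beside them. With an estimated correlation 4 of the 46 kept their call, and with that and the block 0 did (2 to 9 lists per comparison at an unadjusted p under 0.05). Signals under 44.9, the 25th percentile, are not known to lie above background, since no detection calls were used here, so folds against such a mean are given again with an offset of 44.9 added to each signal. Unless stated otherwise, signals are mean ± SD of n = 3 samples at the earlier and then the later time, fold changes come from mean log2 signals, and each adjusted p is from limma with Benjamini-Hochberg adjustment. Each gene named as having risen or fallen went the same way in 3 of 3 pairs of equally numbered samples.

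**Figure D1:**
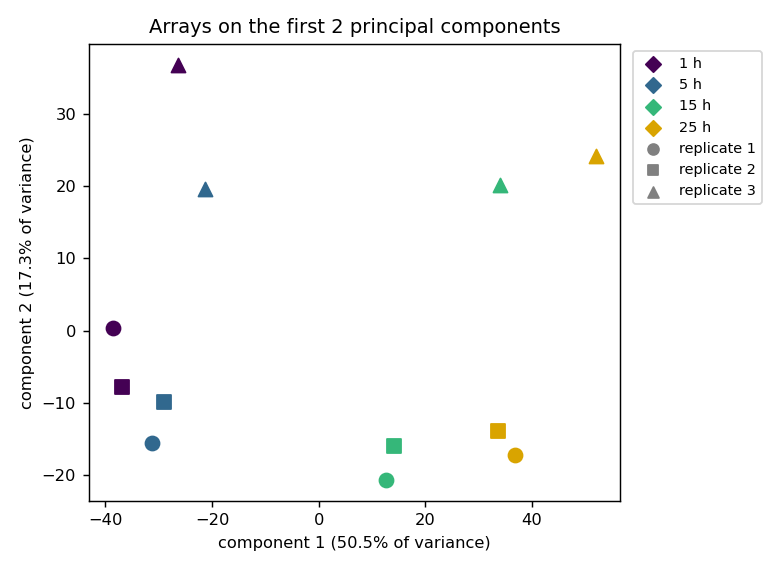
Principal components of the 7379 tested genes, with 1 point per array, colours for hours on Matrigel and shapes for the replicate number. Component 1 (50.5% of the variance) orders the 1 h and 5 h arrays, from -38.6 to -21.3, below the 15 h and 25 h arrays, from 12.7 to 52.1, and component 2 (17.3%) sets replicate 3 (19.6 to 36.8) apart from replicates 1 and 2 (-20.7 to 0.38).

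Over the 4 times, 2576 of 7379 genes (34.9%) changed by limma's F test, and 4069 did with the replicate number as a block. Of the 2576, 1142 had their highest mean at 25 h, 626 at 1 h, 493 at 5 h and 315 at 15 h, while 1002 had their lowest mean at 1 h and 876 at 25 h. The lists of immediate early genes and of SRF and YAP targets, genes switched on by growth factors, serum and cytoskeletal tension, were at their highest at 1 h. The lists of the unfolded protein response and the amino acid response peaked at 5 h, those of DNA replication, mitosis and ribosome biogenesis were lowest at 25 h, and the lysosome list was highest at 25 h. With an estimated correlation the falls of the first lists by 5 h kept their call (adjusted p = 0.0089 and 0.0105), whereas the tests of the others against 1 h gave 0.318 and 0.625 at 5 h, and 0.107, 0.104, 0.0522 and 0.0522 at 25 h, in the order named.

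**Figure D2:**
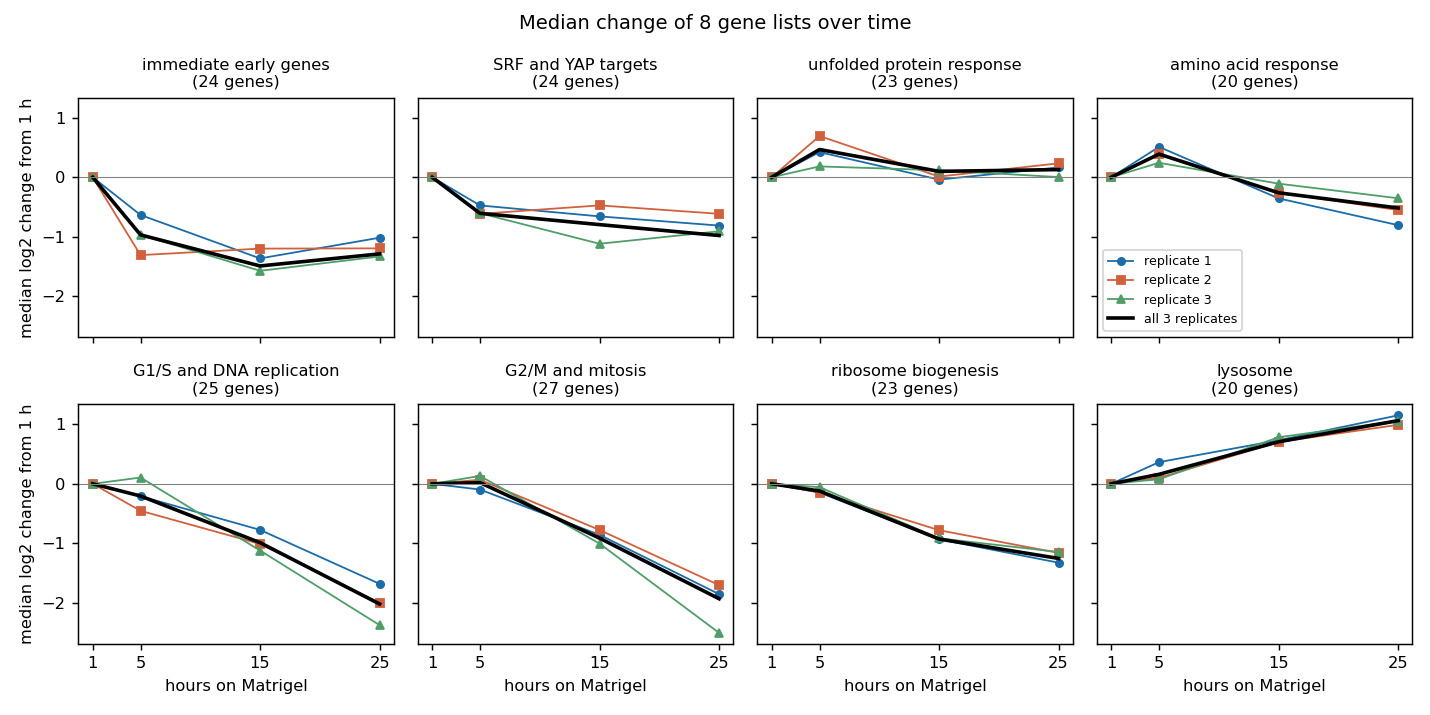
Median log2 change from 1 h of 8 fixed gene lists against hours on Matrigel, with coloured lines for replicates 1, 2 and 3 and a black line for the pooled fit. At 25 h the pooled medians were -2.02 for G1/S and DNA replication, -1.93 for G2/M and mitosis, -1.26 for ribosome biogenesis and 1.06 for the lysosome.

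Most markers of endothelial identity did not pass the brightness filter. Brightness depends on the probe as well as on the transcript, so these shares describe the arrays and rank no cell type above another. Of 28 measured endothelial markers, 4 passed the brightness filter (14.3%, against 59.5% of 12393 named genes; 2-sided Fisher's exact p = 1.52e-06, adjusted p over 32 lists = 2.44e-05). These were Cd34, a sialomucin of vascular and progenitor cells, with a mean signal of 531 over 12 arrays, Gata2 (470.3), Flt1, a receptor of vascular endothelial growth factor (289), and Cdh5, the cadherin of endothelial junctions (181). The brightest probe set of Pecam1 had a mean of 17.9, that of Tie1 1.89 and that of Vwf 1.70. Of 14 fibroblast markers 11 passed (78.6%, adjusted p = 0.23 against all named genes), among them the collagen chains Col1a2 (19436) and Col1a1 (15148), the intermediate filament protein Vim (15293) and S100a4 (9544). Of the pericyte and smooth muscle markers 7 of 15 passed (46.7%, adjusted p = 0.51), with smooth muscle actin, Acta2, at 4223. Of 15 leukocyte markers 4 passed (26.7%, adjusted p = 0.0266), including Cd14 (3601) and Csf1r (2003), and of 8 lymphatic markers 2 passed, Pdpn (3364) and Nrp2 (1012; adjusted p = 0.0995). Markers of epithelium (1 of 15, adjusted p = 0.000132) and neurons (1 of 11, adjusted p = 0.00188) passed less often than genes at large, and 3 of 10 astrocyte markers passed (adjusted p = 0.142).

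**Figure D3:**
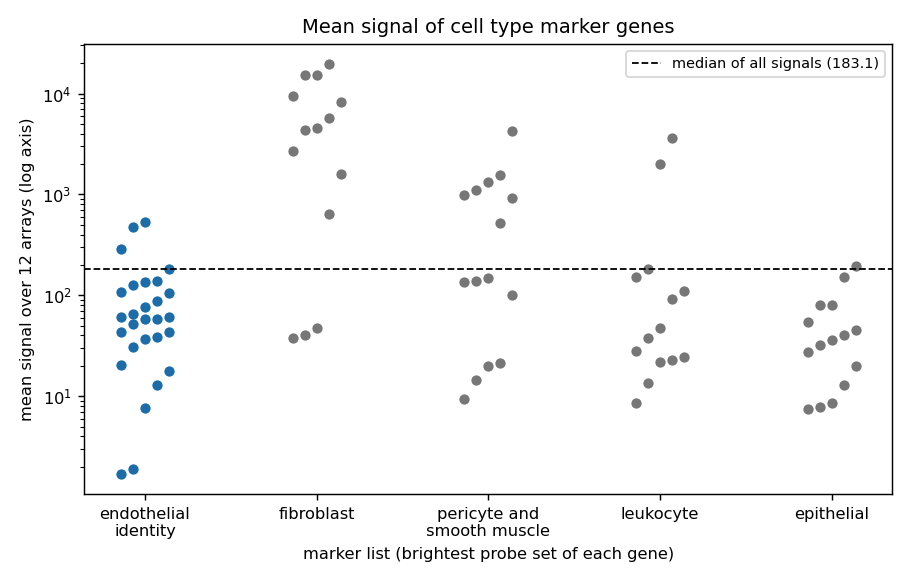
Mean signal over 12 arrays, on a log axis, of each measured marker in 5 lists, taking the brightest probe set per gene, with a dashed line at the median of all signals (183.1). The fibroblast markers reach 19436 (Col1a2), while the brightest endothelial marker, Cd34, lies at 531.

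From 1 to 5 h, genes of the immediate early response fell. Fosb, a subunit of the AP-1 transcription factor, fell 10.6-fold (837 ± 141 to 78.3 ± 9.33; log2 change -3.41 ± 0.28, SE; adjusted p = 0.000133). Its relative Fos fell 5.89-fold (1829 ± 879 to 309 ± 150.2, adjusted p = 0.0073). Egr1, a zinc finger factor induced by growth factors, fell 5.26-fold (10537 ± 639 to 2216 ± 1190.1, adjusted p = 0.00293). Of 24 measured immediate early genes, 7 fell and 0 rose, and 12 fell adjusted over the list alone. The list's median log2 change was -0.97 (adjusted p = 7.29e-17; adjusted p = 0.0089 with an estimated correlation, and 0.0529 with that and the replicate block). SRF and YAP targets, which respond to actin tension, moved with them: 3 of 24 fell and 0 rose, or 7 and 0 adjusted over the list alone. These had a median change of -0.61 (adjusted p = 4.49e-10; adjusted p = 0.0105 with an estimated correlation, and 0.0641 with that and the block), or -0.40 without 1 h array 3. Among these, Fhl2 fell 2.42-fold (1266 ± 92.5 to 528 ± 91.6, adjusted p = 0.0073). F3, the tissue factor that starts coagulation, fell 6.81-fold (921 ± 222 to 134 ± 23.9, adjusted p = 0.000158). Cavin2, a caveolar coat protein, fell 4.72-fold (2629.9 ± 447 to 559 ± 112, adjusted p = 0.000331). The transcriptional regulators Bhlhe40 and Mafk fell 4.02-fold (3375 ± 179 to 843 ± 109.5, adjusted p = 0.000499) and 3.72-fold (adjusted p = 0.000411).

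Cholesterol biosynthesis also fell, with 2 of 18 members lower and 0 higher, or 9 and 0 adjusted over the list alone. Their median change was -0.69 (adjusted p = 2.03e-09; adjusted p = 0.342 with an estimated correlation). Hmgcs1, the synthase upstream of HMG-CoA reductase, fell 3.26-fold (5780.4 ± 2156 to 1763 ± 577, adjusted p = 0.0112). In the opposite direction went the unfolded protein response, the chaperones and folding enzymes of the endoplasmic reticulum: 2 of 23 members rose and 0 fell, or 7 and 0 adjusted over the list alone. Over the list, the median change was 0.47 (adjusted p = 4.46e-06; adjusted p = 0.318 with an estimated correlation). Creld2 rose 2.62-fold (1155 ± 53.9 to 3092 ± 758, adjusted p = 0.00633). The amino acid response list, which shares members with it, moved up with 0 of 20 members past limma's test (7 at an unadjusted p under 0.05), or 6 higher and 0 lower adjusted over the list alone. The median over these genes was 0.39 (adjusted p = 0.00555; adjusted p = 0.625 with an estimated correlation). The G1/S list (25 genes, median -0.21, adjusted p = 0.0235; adjusted p = 0.626 with an estimated correlation) and ribosome biogenesis (23 genes, median -0.12, adjusted p = 0.0281; adjusted p = 0.626 with an estimated correlation) moved down by little, with 0 members past limma's gene test or adjusted over the list alone (0 and 3 at an unadjusted p under 0.05), and the G1/S median within replicate 3 was 0.11. Over 25 other alternatives the adjusted p ran from 2.02e-05 to 0.0626 for the amino acid response (highest without 5 h array 2; median 0.24 without 1 h array 3), from 7.67e-05 to 0.173 for G1/S (lost without 1 h arrays 1 or 2 or 5 h arrays 2 or 3; medians -0.13, -0.08 and -0.34 without 1 h arrays 1, 2 and 3) and from 0.00776 to 0.243 for ribosome biogenesis (lost without 1 h array 1 or 5 h arrays 2 or 3; medians -0.04 and -0.06 without the first 2).

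Tgfb3, a growth factor of the TGF-beta family, rose 5.26-fold (205 ± 93.3 to 1012 ± 278; log2 change 2.40 ± 0.35, SE; adjusted p = 0.00573) by 5 h. Tgfb1 rose 4.10-fold (513 ± 202 to 2011 ± 404, adjusted p = 0.00318). The list of TGF-beta and BMP targets had 3 of 19 members higher and 0 lower, or 5 higher and 2 lower adjusted over the list alone. Across its members, the median change was 0.45 (adjusted p = 0.0636, and 0.0309 with the replicate block; adjusted p = 0.625 with an estimated correlation). Flt1 rose 4.17-fold (132 ± 47.8 to 540.4 ± 145, adjusted p = 0.00536); of its 2 other probe sets 1 also rose. Ggct, an enzyme of glutathione breakdown, rose 5.87-fold (165 ± 30.3 to 1008 ± 402, adjusted p = 0.000944). The phosphatase gene Ptpn22 rose 3.76-fold (243 ± 49.2 to 947 ± 357, adjusted p = 0.00647) and Abhd1 3.43-fold (adjusted p = 0.00448). Gsta4, a glutathione transferase, rose 2.35-fold (691 ± 149.9 to 1602 ± 132, adjusted p = 0.00791) as 1 of 18 tested NRF2 targets, or 2 adjusted over the list alone. For the list, the median change was 0.24 (adjusted p = 0.0636, and 0.0284 with the block; adjusted p = 0.625 with an estimated correlation).

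At 5 h, 122 of 7379 genes (1.65%) differed from 1 h, 65 higher and 57 lower, of which 90 by at least 2-fold, and 573 differed with the replicate block (331 higher, 242 lower). In 1368 genes (18.5%, where chance gives 10%) the 3 samples of each time did not overlap. Of the 20 largest changes 7 lost their call in fits without 1 array, among them a rise of the matricellular gene Smoc2 (7.05-fold) and a fall of Thbs1, an inhibitor of angiogenesis (6.74-fold): Smoc2 without 1 h arrays 1 and 2 and 5 h arrays 1, 2 and 3 (up to 0.115), and Thbs1 without 1 h arrays 1, 2 and 3, 5 h arrays 1 and 2, 15 h arrays 1 and 2 and 25 h arrays 1 and 2 (up to 0.152). The count was 37, 57 and 65 without 1 h arrays 1, 2 and 3, and 51, 34 and 63 without 5 h arrays 1, 2 and 3; without all arrays numbered 1, left out after the data were seen, it was 3, or 152 with the block, and 17 of the 20 largest changes lost their call (adjusted p 0.0877 to 0.404), or 3 of them with the block. Smoc2 also lost it with the offset (0.0564, range over 24 alternatives 0.000765 to 0.29). Moves of over 1.5 times gave folds of 12.8 for Thbs1 without 5 h array 3. After adding the offset, the fold was 3.85 for Smoc2.

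By 15 h, genes of proliferation and of ribosome production had fallen and lysosomal genes had risen. Of 25 genes of G1/S and DNA replication, 17 were lower and 0 higher than at 1 h, or 21 and 0 adjusted over the list alone. Taking all tested members, the median log2 change was -0.99 (adjusted p = 9.7e-12; adjusted p = 0.207 with an estimated correlation). Mcm3, a subunit of the replicative helicase, fell 3.23-fold (2378 ± 310.2 to 743 ± 146; log2 change -1.69 ± 0.23, SE; adjusted p = 0.000567). Mcm2, another subunit, fell 2.23-fold (2772 ± 260.4 to 1266 ± 302, adjusted p = 0.00226). Of 27 mitotic genes 17 fell and 0 rose, or 20 and 0 adjusted over the list alone. The median over these genes was -0.91 (adjusted p = 2.63e-11; adjusted p = 0.207 with an estimated correlation). The mitotic kinase Plk1 fell 1.89-fold (1744 ± 97.0 to 922 ± 88.4, adjusted p = 0.00282). Ribosome biogenesis fell in 20 of 23 genes, 22 adjusted over the list alone, with 0 higher by either count. The list as a unit had a median of -0.93 (adjusted p = 4.28e-15; adjusted p = 0.0725 with an estimated correlation). Nolc1, a nucleolar phosphoprotein, fell 3.00-fold (1863 ± 123 to 631 ± 149, adjusted p = 0.000271). Of 20 lysosomal genes 12 rose and 0 fell, or 16 and 0 adjusted over the list alone, and 6 rose after median centring. Measured members had a median change of 0.71 (adjusted p = 1.18e-05; adjusted p = 0.0725 with an estimated correlation). Gaa, lysosomal alpha-glucosidase, rose 2.22-fold (700.1 ± 68.9 to 1551 ± 143, adjusted p = 0.00352).

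Genes of the early response were lower at 15 h than at 1 h, and contractile and inflammatory genes were lower too. Immediate early genes had 15 of 24 members lower and 1 higher, or 17 and 1 adjusted over the list alone. The list's median change was -1.49 (adjusted p = 5.37e-09; adjusted p = 0.0398 with an estimated correlation, and 0.102 with that and the replicate block). Fosb fell 9.10-fold (adjusted p = 4.97e-05). The phosphatase gene Dusp2 fell 5.76-fold (5673 ± 1895 to 953 ± 70.8, adjusted p = 0.000304). SRF and YAP targets fell in 10 of 24 genes, 11 adjusted over the list alone, with 0 higher. These had a median change of -0.80 (adjusted p = 1.14e-08; adjusted p = 0.0395 with an estimated correlation, and 0.102 with that and the block). Tagln and Acta2, actin-binding and actin genes of smooth muscle that also stand in the pericyte list, fell 5.48-fold (2886 ± 1505 to 529 ± 268, adjusted p = 0.00362) and 5.01-fold (adjusted p = 0.00662). Cnn1, calponin, fell 6.44-fold (adjusted p = 0.00447). Of 7 pericyte and smooth muscle genes 4 fell and 1 rose by both counts. Their median change was -1.48 (adjusted p = 0.0314; adjusted p = 0.207 with an estimated correlation, and 0.00171 to 0.212 over 25 other alternatives, with 0.0615 without 15 h array 1). It was -0.32 without the brightness filter (adjusted p = 0.212) and -2.77 without 15 h array 3. Inflammatory and NF-kB genes fell in 11 of 24 cases and rose in 2, or 14 and 2 adjusted over the list alone. Over the list, the median change was -1.06 (adjusted p = 0.000106; adjusted p = 0.393 with an estimated correlation). The chemokine Ccl20 fell 22.8-fold (423 ± 211 to 17.2 ± 2.41, adjusted p = 0.00271) and Tnfaip3, a brake on NF-kB, 6.29-fold (adjusted p = 0.00157), whereas the chemokine Ccl5 rose 3.84-fold (adjusted p = 0.00155). Folds moved by over 1.5 times to 4.28 for Cnn1 without 1 h array 3. On the scale with the offset the fold was 7.05 for Ccl20.

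Cholesterol biosynthesis fell in 8 of 18 genes, 10 adjusted over the list alone, with 0 higher. Across its members, the median change was -0.81 (adjusted p = 9.52e-08; adjusted p = 0.207 with an estimated correlation). Of 14 integrin and adhesion genes 4 fell and 2 rose, or 6 and 2 adjusted over the list alone. The median over these genes was -0.33 (adjusted p = 0.0204; adjusted p = 0.207 with an estimated correlation, and 0.00872 to 0.0665 over 25 other alternatives), or -0.50 without 15 h array 2 and, no longer called, after median centring. The hyaluronan receptor Cd44 fell 3.82-fold (3560.3 ± 239.7 to 969.8 ± 328, adjusted p = 0.00069). The cytokine Lif fell 8.51-fold (5375 ± 1379.7 to 763 ± 493, adjusted p = 0.00728). Hes1, a repressor induced by Notch, fell 5.78-fold (1852 ± 1239.6 to 280.4 ± 63.7, adjusted p = 0.000834) and Kcnip1 5.93-fold (adjusted p = 0.000346). Among the largest rises, Lcn2, a siderophore-binding lipocalin, rose 27.8-fold (47.6 ± 16.8 to 2079 ± 2499; log2 change 4.80 ± 1.00, SE; adjusted p = 0.00526). On 1 h array 2 the Lcn2 signal was 28.4, under 44.9. The metalloreductase Steap4 rose 16.9-fold (102 ± 98.1 to 1428 ± 911, adjusted p = 0.00364). Ifitm6 rose 16.6-fold (30.6 ± 4.16 to 527 ± 195, adjusted p = 4.44e-05). A4galt, a glycolipid galactosyltransferase, rose 16.5-fold (adjusted p = 0.000419). Folds that moved by over 1.5 times were 11.2 for Steap4 without 1 h array 2; 28.6 for Steap4 and 29.2 for A4galt without 1 h array 3; 5.15 for Lif and 13.97 for Lcn2 without 15 h array 3. With the offset the fold was 7.31 for Ifitm6 and 6.14 for A4galt.

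Genes of the extracellular matrix were among those that rose by 15 h, although their lists passed no test without the block. Of 18 microfibril and matricellular genes 5 rose and 1 fell by both counts. Across its members, the median change was 0.47 (adjusted p = 0.208). Thbs2 rose 4.08-fold (246 ± 79.6 to 1039.7 ± 494, adjusted p = 0.00247). The proteoglycan Dcn rose 7.72-fold (849 ± 737 to 6118 ± 4585, adjusted p = 0.00651), and Smoc2, outside the list, 11.9-fold (adjusted p = 0.00112). Of 11 fibroblast markers 3 rose and 0 fell by both counts, Dcn, Prrx1, 1.69-fold (adjusted p = 0.00712), and the collagen chain Col3a1, 2.87-fold (adjusted p = 0.0285), with a list median of 0.23 (adjusted p = 0.335), or 0.06 after median centring. Without 1 array, Col3a1 without 1 h array 3 and 15 h arrays 1 and 2 (up to 0.0883) missed the threshold, as did Prrx1 (up to 0.0603) and Col3a1 (up to 0.104) without all arrays numbered 1 or 3, the highest over 25 alternatives. Of 18 collagen genes 6 rose and 0 fell by both counts. For the list, the median change was 0.25 (adjusted p = 0.0778, and 0.0249 with the replicate block; adjusted p = 0.528 with an estimated correlation). Col6a2 rose 2.15-fold (3485 ± 313 to 7499 ± 507, adjusted p = 0.000861). Matrix proteases and inhibitors had 7 of 19 genes higher and 3 lower by both counts. Taking all tested members, the median change was 0.24 (adjusted p = 0.336). Among its members, the stromelysin Mmp10 rose 13.2-fold (74.4 ± 63.3 to 910.4 ± 537, adjusted p = 0.00199) and Mmp11 5.48-fold (adjusted p = 0.000844). Mgst2, a glutathione transferase, rose 12.6-fold (87.4 ± 51.7 to 923 ± 88.6, adjusted p = 0.000397). Xdh, xanthine dehydrogenase, rose 10.3-fold (adjusted p = 0.00113). The NRF2 list had 5 of 18 genes higher and 1 lower, or 7 and 2 adjusted over the list alone. For the list, the median change was 0.36 (adjusted p = 0.159). The amino acid response had 3 of 20 genes higher and 4 lower by both counts. The list as a unit had a median of -0.26 (adjusted p = 0.0739, and 0.0226 with the block; adjusted p = 0.528 with an estimated correlation). Interferon response genes had 1 of 16 higher by both counts. Taking all tested members, the median change was 0.76 (adjusted p = 0.245, and 0.023 with the block; adjusted p = 0.766 with an estimated correlation). Moves of over 1.5 times gave folds of 8.56 for Mmp10 without 1 h array 1; 21.1 for Mmp10 without 1 h array 2; 12.3 for Dcn and 7.91 for Mgst2 without 1 h array 3; 21.3 for Mmp10 without 15 h array 3. After adding the offset, the fold was 6.15 for Smoc2 and 4.99 for Xdh.

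In all, 1756 genes (23.8%) differed between 15 and 1 h, 1133 higher and 623 lower, of which 806 by at least 2-fold (525 higher, 281 lower), and 2969 differed with the block (1855 higher, 1114 lower). In 3009 genes (40.8%, where chance gives 10% for unpaired samples) the samples did not overlap. The median gene lay 0.12 log2 above 1 h, and after centring each array on its median it lay at -0.06 and the split was 654 higher of 1567 (41.7%), against 64.5% higher in the deposited scaling. The count was 1138 without 1 h array 1 and 1054 without 15 h array 3; without all arrays numbered 1 it was 470, and without those numbered 3 it was 1148, both chosen after the data were seen. Without those numbered 1, 10 of the 20 largest changes lost their call, or 0 with the block: Lcn2 (0.0582), Ccl20 (0.0626), Steap4 (0.0646), Mmp10 (0.0648), Atoh8 (0.0696), Hbegf (0.0736), Lif and Cnn1 (0.0791 each), Myl9 (0.14) and Nt5e (0.165), each the highest adjusted p over the alternatives of its gene, as did Tagln (0.0508), Dcn (0.0684) and Acta2 (0.108). Among the 20 largest changes were Nt5e, an enzyme that makes adenosine (16.4-fold up), the growth factor Hbegf (8.95-fold down) and the myosin light chain Myl9 (7.12-fold down), which lost their call without 1 array: Nt5e without 1 h array 1 and 15 h array 2 (up to 0.0577), Hbegf without 1 h array 1 (up to 0.0501), and Myl9 without 1 h array 3 and 15 h arrays 1 and 2 (up to 0.0554); the remaining rise was that of the transcription factor Atoh8 (10.5-fold). Folds moved by over 1.5 times to 6.38 for Atoh8 without 1 h array 2; 14.5 for Hbegf, 4.44 for Myl9 and 16.9 for Atoh8 without 1 h array 3; 5.40 for Hbegf and 10.8 for Myl9 without 15 h array 3. On the scale with the offset the fold was 5.38 for Nt5e and 4.67 for Atoh8.

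At 25 h, the latest time, the fall of cell cycle genes covered whole lists. All 27 mitotic genes fell, also adjusted over the list alone. The list as a unit had a median of -1.93 (adjusted p = 3.09e-20; adjusted p = 0.104 with an estimated correlation). Plk1 fell 5.89-fold (1744 ± 97.0 to 300.3 ± 65.5; log2 change -2.56 ± 0.17, SE; adjusted p = 4.07e-06). Top2a, the topoisomerase of dividing cells, fell 5.43-fold (3507 ± 353 to 674 ± 229, adjusted p = 3.69e-05). Of 25 G1/S and replication genes 24 fell, or 25 adjusted over the list alone. Measured members had a median change of -2.02 (adjusted p = 3.32e-18; adjusted p = 0.107 with an estimated correlation). Mcm3 fell 8.24-fold (2378 ± 310.2 to 296 ± 85.0, adjusted p = 5.06e-06) and Mcm2 by a log2 change of -2.20 (adjusted p = 1.74e-05). Outside these lists, the repressor E2f8 fell 28.0-fold (370.5 ± 36.6 to 14.7 ± 8.19, adjusted p = 3.32e-05). Pole, the catalytic subunit of DNA polymerase epsilon, fell 10.1-fold (adjusted p = 0.001). The cohesin protector Sgo1 fell 8.96-fold (adjusted p = 0.00112). Thymidine kinase, Tk1, a member of the G1/S list, fell 8.86-fold (adjusted p = 0.000501). Ribosome biogenesis fell in 21 of 23 genes, 22 adjusted over the list alone, with 0 higher. Measured members had a median change of -1.26 (adjusted p = 3.14e-16; adjusted p = 0.0522 with an estimated correlation). Rrp12 fell 34.3-fold (263 ± 17.1 to 7.83 ± 1.95, adjusted p = 7e-06). Folds that moved by over 1.5 times were 5.62 for Pole, 5.61 for Tk1 and 4.68 for Sgo1 without 25 h array 3. With the offset the fold was 6.99 for E2f8 and 5.84 for Rrp12.

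Lysosomal genes stood higher at 25 h than at 1 h in 17 of 20 cases, 18 adjusted over the list alone, with 0 lower. The list's median change was 1.06 (adjusted p = 8.19e-07; adjusted p = 0.0522 with an estimated correlation). Gaa rose 3.30-fold (700.1 ± 68.9 to 2318 ± 293; log2 change 1.72 ± 0.22, SE; adjusted p = 0.000108). Among single genes, Lcn2 rose 127-fold (47.6 ± 16.8 to 6688 ± 4683, adjusted p = 0.000238). Haptoglobin, Hp, rose 76.2-fold (6.63 ± 1.46 to 504 ± 93.9, adjusted p = 0.00222). Xdh rose 31.4-fold (42.8 ± 30.4 to 1252 ± 662, adjusted p = 3.69e-05). Matrix Gla protein, Mgp, an inhibitor of calcification, rose 20.4-fold (594 ± 587 to 8382 ± 3409, adjusted p = 0.00264). The reductases Dcxr and Cbr2 rose 23.6-fold (adjusted p = 3.69e-05) and 20.5-fold (adjusted p = 0.00306), and Mgst2 20.4-fold (adjusted p = 3.69e-05). Steap4 rose 27.7-fold (adjusted p = 0.000602), Ifitm6 29.9-fold (adjusted p = 4.07e-06) and the phosphodiesterase Gdpd2 36.6-fold (adjusted p = 0.000599). Moves of over 1.5 times gave folds of 24.4 for Gdpd2 without 1 h array 1; 11.03 for Mgp, 18.5 for Steap4 and 21.98 for Gdpd2 without 1 h array 2; 36.4 for Mgp, 34.2 for Cbr2, 12.8 for Mgst2, 46.99 for Steap4 and 91.4 for Gdpd2 without 1 h array 3. After adding the offset, the fold was 10.5 for Hp, 14.1 for Xdh and 12.6 for Ifitm6.

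Immediate early genes were lower at 25 h than at 1 h in 16 of 24 cases with 1 higher, or 18 and 1 adjusted over the list alone. The list's median change was -1.29 (adjusted p = 1.4e-06; adjusted p = 0.0522 with an estimated correlation). SRF and YAP targets were lower in 10 of 24 cases with 0 higher, or 12 and 0 adjusted over the list alone. These had a median change of -0.98 (adjusted p = 4.73e-06; adjusted p = 0.0522 with an estimated correlation). Fosb fell 8.89-fold (adjusted p = 1.25e-05) and Tagln 7.43-fold (adjusted p = 0.000584). Arc, an activity-induced gene, fell 9.30-fold (5509.7 ± 2401 to 565 ± 183, adjusted p = 3.69e-05). Cholesterol biosynthesis fell in 12 of 18 genes, 13 adjusted over the list alone, with 0 higher. Its median change was -1.01 (adjusted p = 1.63e-05; adjusted p = 0.308 with an estimated correlation), or -0.53 without 25 h array 3. In the amino acid response 9 of 20 genes fell and 2 rose by both counts. Their median change was -0.52 (adjusted p = 0.00171; adjusted p = 0.308 with an estimated correlation). The neutral amino acid transporter Slc7a5 fell 7.48-fold (2695 ± 492 to 367 ± 109, adjusted p = 1.87e-05). Inflammatory and NF-kB genes fell in 12 of 24 cases and rose in 4 by both counts, or in 1 after median centring. Over the list, the median change was -0.97 (adjusted p = 0.00508; adjusted p = 0.528 with an estimated correlation, and 0.000205 to 0.0586 over 25 other alternatives). The chemokines Ccl20, Cxcl2 and Ccl2 fell 19.0-fold (adjusted p = 0.00171), 8.39-fold (adjusted p = 0.000548) and 6.80-fold (adjusted p = 0.000623). The cytokine Lif, also a member of the list, fell 13.3-fold (adjusted p = 0.00126). Heat shock genes fell in 6 of 15 cases with 0 higher by both counts. The median over these genes was -0.35 (adjusted p = 0.00534; adjusted p = 0.0572 with an estimated correlation), or -0.55 after median centring. Folds moved by over 1.5 times to 7.86 for Lif without 25 h array 3. On the scale with the offset the fold was 6.68 for Ccl20.

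Adhesion and matrix genes moved in both directions by 25 h. Of 14 integrin and adhesion genes 5 fell and 1 rose, or 7 and 1 adjusted over the list alone. Their median change was -0.50 (adjusted p = 0.0273; adjusted p = 0.262 with an estimated correlation, and 0.0109 to 0.0672 over 25 other alternatives, the highest without 1 h array 3). Cd44 fell 5.02-fold (3560.3 ± 239.7 to 723 ± 171, adjusted p = 6.42e-05) and Itgb5 rose 2.80-fold (adjusted p = 0.000492); the desmosomal plakophilin Pkp1, outside the list, fell 10.6-fold (adjusted p = 0.00256). Of 7 pericyte and smooth muscle genes 3 fell and 0 rose by both counts. Across its members, the median change was -1.07 (adjusted p = 0.0412; adjusted p = 0.226 with an estimated correlation, and 0.00781 to 0.449 over 25 other alternatives, with up to 0.0764 without 1 h array 3 or 25 h array 1). Without the brightness filter its median was 0.24, the opposite direction (adjusted p = 0.449), and without the arrays numbered 3 it was -0.67. Microfibril and matricellular genes rose in 9 of 18 cases and fell in 2, or 10 and 3 adjusted over the list alone. For the list, the median change was 0.61 (adjusted p = 0.0979, and 0.0428 with the replicate block; adjusted p = 0.308 with an estimated correlation). Thbs2 rose 7.52-fold (246 ± 79.6 to 1810.1 ± 363, adjusted p = 9.49e-05). Collagens rose in 6 of 18 cases with 0 lower by both counts, and in 3 after median centring. Over the list, the median change was 0.30 (adjusted p = 0.114, and 0.0415 with the block; adjusted p = 0.569 with an estimated correlation). Fibroblast markers rose in 5 of 11 cases and fell in 1, or 6 and 1 adjusted over the list alone (median 0.60, adjusted p = 0.187), with the surface glycoprotein Thy1 up 2.95-fold (adjusted p = 0.00287) and Prrx1 1.91-fold (adjusted p = 0.00107); 5 of the list's 15 genes also stand in another list. Matrix proteases and inhibitors rose in 7 of 19 cases and fell in 3 by both counts. Taking all tested members, the median change was 0.54 (adjusted p = 0.148). Of 16 interferon response genes 1 rose, or 0 adjusted over the list alone and 0 under either other scaling. The median over these genes was 0.90 (adjusted p = 0.148, and 0.0133 with the block; adjusted p = 0.718 with an estimated correlation). Folds that moved by over 1.5 times were 6.93 for Pkp1 without 1 h array 1; 17.3 for Pkp1 without 1 h array 3. With the offset the fold was 5.65 for Pkp1.

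Genes of sprouting and Notch signalling showed no common direction at 25 h. Of 14 tip cell and sprouting genes 5 rose and 3 fell, or 6 and 3 adjusted over the list alone. Across its members, the median change was 0.36 (adjusted p = 0.669). The guidance ligand Slit2 rose 4.24-fold (1005 ± 380.4 to 4208 ± 1502, adjusted p = 0.000471). Of 11 Notch pathway genes 2 fell and 0 rose by both counts, Hes1 by 8.25-fold (adjusted p = 7.88e-05) and the ligand Dll4 by 8.29-fold (adjusted p = 0.0124); the list's median was 0.07, its mean -0.50 and its test downward (adjusted p = 0.459). Flt1 was 2.01-fold (132 ± 47.8 to 254 ± 20.7, adjusted p = 0.0162) higher than at 1 h, the 1 change among the 4 tested endothelial markers, of which 0 passed after median centring (Flt1 at 0.0569). Without 1 array, Dll4 without 1 h array 1 and 25 h array 2 (up to 0.064) and Flt1 without 1 h array 2 (up to 0.0672) missed the threshold, as did Dll4 with no filter (0.314, range over 24 alternatives 0.000147 to 0.314) and Flt1 without the arrays numbered 3 (0.0884, range over 24 alternatives 0.00251 to 0.0884). Of 12 basement membrane genes 3 rose and 0 fell by both counts, or 2 and 1 after median centring. The list as a unit had a median of 0.12 (adjusted p = 0.577). Moves of over 1.5 times gave folds of 4.77 for Dll4 without 1 h array 1; 14.99 for Dll4 without 1 h array 3; 13.1 for Dll4 without 25 h array 1; 4.89 for Dll4 without 25 h array 2. After adding the offset, the fold was 3.92 for Dll4.

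At 25 h, 2705 genes (36.7%) differed from 1 h, 1591 higher and 1114 lower, of which 1406 by at least 2-fold (833 higher, 573 lower), and 3778 did with the block. In 3567 genes (48.3%, where chance gives 10% for unpaired samples) the samples did not overlap. The median gene lay 0.13 log2 above 1 h, and after centring each array on its median it lay at -0.06 and 1021 of 2483 changed genes (41.1%) were higher, against 58.8% in the deposited scaling. Without all arrays numbered 1, left out after the data were seen, 1559 genes differed, and of the 20 largest changes Cbr2 (adjusted p = 0.0625, range over 25 alternatives 4.01e-06 to 0.0625) and Pkp1 (0.0667, range over 24 alternatives 1.11e-05 to 0.0667) missed the threshold.

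**Figure D4:**
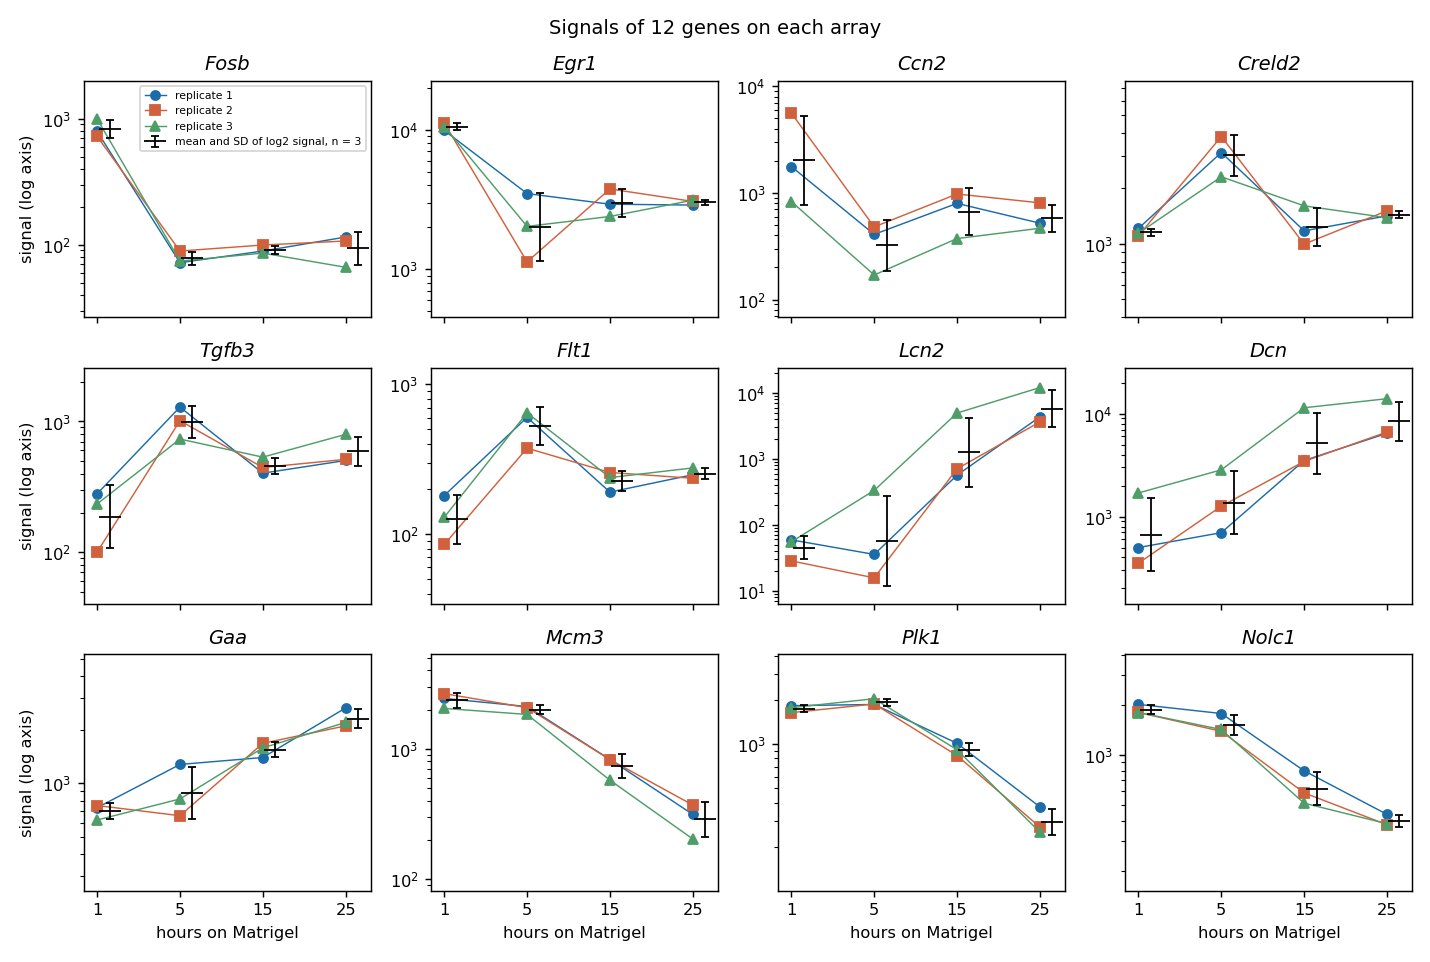
Signals of 12 genes on a log axis against hours on Matrigel, with 1 point per array and the mean and SD of log2 signal (n = 3). Fosb drops from a mean of 837 at 1 h to 78.3 at 5 h, Creld2 peaks at 5 h (3092), Plk1 lies at 1744 at 1 h and 300.3 at 25 h, and Lcn2 goes from 47.6 at 1 h to 6688 at 25 h.

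Between 5 and 15 h, ribosome biogenesis fell in 16 of 23 genes, 21 adjusted over the list alone, with 0 higher. Measured members had a median log2 change of -0.85 (adjusted p = 5.52e-14; adjusted p = 0.19 with an estimated correlation). Nolc1 fell 2.44-fold (1520.4 ± 214 to 631 ± 149; log2 change -1.28 ± 0.18, SE; adjusted p = 0.002). Mitotic genes fell in 13 of 27 cases, 18 adjusted over the list alone and 20 after median centring, with 0 higher. The list's median change was -0.87 (adjusted p = 1.76e-12; adjusted p = 0.241 with an estimated correlation). The kinase Aurka fell 2.79-fold (1554 ± 59.8 to 564 ± 106, adjusted p = 0.00368) and Plk1 2.09-fold (adjusted p = 0.00273). Of 25 G1/S genes 7 fell, or 11 adjusted over the list alone, with 0 higher; 15 fell after median centring and 5 after quantile normalization. These had a median change of -0.76 (adjusted p = 1.15e-09; adjusted p = 0.272 with an estimated correlation). Mcm3 fell 2.73-fold (adjusted p = 0.00273). Lysosomal genes rose in 7 of 20 cases, 10 adjusted over the list alone and 2 after median centring, with 0 lower. Their median change was 0.58, or 0.38 after median centring (adjusted p = 4.62e-05; adjusted p = 0.19 with an estimated correlation).

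The stress programmes that had gone up by 5 h went down again by 15 h. Unfolded protein response genes fell in 8 of 23 cases, 12 adjusted over the list alone and 13 after median centring, with 0 higher. For the list, the median change was -0.51 (adjusted p = 2.26e-06; adjusted p = 0.241 with an estimated correlation). Creld2 fell 2.45-fold (3092 ± 758 to 1262 ± 314, adjusted p = 0.00273). The amino acid response fell in 8 of 20 genes with 0 higher, or 10 and 1 adjusted over the list alone. Over the list, the median change was -0.50 (adjusted p = 3.8e-05; adjusted p = 0.241 with an estimated correlation). Slc7a5 fell 4.17-fold (3763 ± 907 to 902 ± 221, adjusted p = 0.00196). Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases, fell 9.95-fold (3082 ± 1113 to 309 ± 100.2, adjusted p = 0.002), though its other probe set was not called. Inflammatory and NF-kB genes fell in 6 of 24 cases, 10 adjusted over the list alone and 10 after median centring, with 0 higher. The median over these genes was -0.70 (adjusted p = 9.98e-05; adjusted p = 0.375 with an estimated correlation), or -0.42 without 5 h array 3. Other large falls were those of the semaphorin Sema7a, 6.45-fold (adjusted p = 0.00677), and the kinase Stk10, 5.70-fold (adjusted p = 0.00293).

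Of 18 microfibril and matricellular genes 2 rose and 0 fell by both counts. Across its members, the median change was 0.42 (adjusted p = 0.0241; adjusted p = 0.241 with an estimated correlation, and 0.000688 to 0.12 over 25 other alternatives, the highest without 5 h array 2). It was 0.21 after median centring, and 0.65 and 0.64 without 5 h array 3 and 15 h array 1. Thbs2 rose 4.81-fold (adjusted p = 0.00273). Collagens had 1 of 18 genes higher by both counts, Col6a2, 1.68-fold (adjusted p = 0.0114), or 0 after median centring (0.0945 for Col6a2, range over 25 alternatives 0.000829 to 0.103). For the list, the median change was 0.40 (adjusted p = 0.0737, and 0.00764 with the replicate block; adjusted p = 0.538 with an estimated correlation). Of 11 fibroblast markers 1 rose by both counts, the homeobox gene Prrx1, 1.95-fold (adjusted p = 0.00385). Taking all tested members, the median change was 0.45 (adjusted p = 0.0584, and 0.00401 with the block; adjusted p = 0.375 with an estimated correlation). The pericyte list had 3 of 7 genes lower and 0 higher, or 3 and 1 adjusted over the list alone. Taking all tested members, the median change was -0.78 (adjusted p = 0.039; adjusted p = 0.241 with an estimated correlation, and 0.000904 to 0.126 over 25 other alternatives, with up to 0.0726 without 5 h arrays 1 or 3 or 15 h array 1), and -1.68, -2.15 and -1.58 without 5 h array 1, 15 h array 3 and all arrays numbered 3. Tagln fell 4.68-fold (adjusted p = 0.01). Interferon response genes had 1 of 16 higher, 3 adjusted over the list alone and 0 after median centring, with 0 lower. The list as a unit had a median of 0.76 (adjusted p = 0.048; adjusted p = 0.628 with an estimated correlation, and 0.000361 to 0.383 over 25 other alternatives, the call being lost without 5 h arrays 1 or 2, 15 h array 3 or 25 h array 2), and 0.50, 1.31 and 0.41 without 5 h arrays 1 and 3 and 15 h array 3. Xdh rose 9.82-fold (adjusted p = 0.00273). Ifitm6 rose 8.51-fold (61.2 ± 17.7 to 527 ± 195, adjusted p = 0.000401). The mTOR-binding protein Deptor rose 8.38-fold (46.8 ± 27.7 to 371 ± 147, adjusted p = 0.00258). On the scale with the offset the fold was 4.96 for Xdh.

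Between 5 and 15 h, 1068 genes (14.5%) changed, 644 higher and 424 lower, of which 457 by at least 2-fold (313 higher, 144 lower), and 2415 changed with the block (1429 higher, 986 lower). In 2612 genes (35.4%, where chance gives 10%) the samples did not overlap. After centring each array on its median, the median gene lay at -0.13 log2 and 325 of 1193 changed genes (27.2%) were higher, against 60.3% in the deposited scaling. Of the 10 largest changes 4 lost their call without 1 array, among them the rises of Lcn2 (log2 change 4.46) and Steap4 (8.07-fold): Lcn2 without 5 h array 2 and 15 h array 3 (up to 0.0525), and Steap4 without 5 h arrays 1 and 2 and 15 h arrays 2 and 3 (up to 0.097). The count was 566 without 5 h array 2, 671 without 5 h array 3, 656 without 15 h array 1 and 470 without 15 h array 3; in fits chosen after the data were seen it was 3 without all arrays numbered 1, or 1339 with the block, and 601 without those numbered 3. Without those numbered 1, 9 of the 10 largest changes lost their call (0.0568 to 0.18), or 1 with the block. Folds moved by over 1.5 times to 11.6 for Lcn2 and 5.00 for Steap4 without 5 h array 2; 53.2 for Lcn2 and 15.9 for Steap4 without 5 h array 3; 11.1 for Lcn2 without 15 h array 3.

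From 15 to 25 h, cell cycle genes fell further. Mitotic genes fell in 11 of 27 cases, or all 27 adjusted over the list alone. Measured members had a median log2 change of -1.21 (adjusted p = 9.14e-37; adjusted p = 0.0759 with an estimated correlation). Plk1 fell 3.11-fold (922 ± 88.4 to 300.3 ± 65.5; log2 change -1.64 ± 0.17, SE; adjusted p = 0.00121). Cyclin F, Ccnf, fell 3.38-fold (406 ± 122 to 117 ± 10.9, adjusted p = 0.00183). The SHC-binding protein Shcbp1 fell 3.72-fold (673 ± 20.6 to 193 ± 76.0, adjusted p = 0.00392). Of 25 G1/S genes 6 fell, or 21 adjusted over the list alone, with 0 higher. The list's median change was -1.02 (adjusted p = 7.33e-27; adjusted p = 0.0759 with an estimated correlation). Ribosome biogenesis fell in 2 of 23 genes, 8 adjusted over the list alone, with 0 higher. The list as a unit had a median of -0.31 (adjusted p = 9.08e-11; adjusted p = 0.115 with an estimated correlation). Rrp12 fell 8.98-fold (adjusted p = 0.00253). In the amino acid response 3 of 20 genes fell and 0 rose, or 8 and 1 adjusted over the list alone. Measured members had a median change of -0.62 (adjusted p = 6.07e-06; adjusted p = 0.184 with an estimated correlation). Asparagine synthetase, Asns, fell 2.11-fold (adjusted p = 0.0189). Without 1 array, Asns without 15 h arrays 1 and 2 and 25 h arrays 1 and 3 (up to 0.127) missed the threshold, and with averaged probe sets too (0.0682, range over 25 alternatives 0.000833 to 0.488). Heat shock genes fell in 1 of 15 cases, 2 adjusted over the list alone, with 0 higher. These had a median change of -0.19 (adjusted p = 0.00961; adjusted p = 0.0759 with an estimated correlation). With the offset the fold was 2.17 for Rrp12.

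The lysosome list moved up once more, although 0 of its 20 genes passed limma's test over all genes or adjusted over the list alone (5 at an unadjusted p under 0.05). The list moved by a median of 0.29 (adjusted p = 1.21e-05; adjusted p = 0.0759 with an estimated correlation). The hypoxia and glycolysis list did so as well with 0 of 18 genes past either test (3 at an unadjusted p under 0.05). Their median change was 0.21 (adjusted p = 0.0365, and 0.0786 with the replicate block; adjusted p = 0.354 with an estimated correlation, and 0.00641 to 0.345 over 25 other alternatives, the call being lost without 1 h array 3, 15 h array 2 or 25 h arrays 1 or 3), and 0.11, 0.08 and 0.13 without 15 h array 2, 25 h array 3 and all arrays numbered 1. Microfibril and matricellular genes had 0 of 18 past the test (3 at an unadjusted p under 0.05), or 1 higher adjusted over the list alone. Over the list, the median change was 0.20 (adjusted p = 0.0738, and 0.0303 with the block; adjusted p = 0.354 with an estimated correlation). Clu, clusterin, an extracellular chaperone, rose 3.65-fold (490.4 ± 92.0 to 1789.7 ± 345, adjusted p = 0.00121), but 0 of its 3 other probe sets were called.

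In all, 57 genes (0.772%) differed between 25 and 15 h, 2 higher and 55 lower, and 314 did with the block (88 higher, 226 lower); in 1048 genes (14.2%, where chance gives 10%) the samples did not overlap. The other gene that rose was Tnfrsf9, a receptor of the tumour necrosis factor family (2.02-fold), and the largest falls included that of the checkpoint kinase Bub1 (3.58-fold). Of the 7 largest changes 4 lost their call without 1 array, among them Tnfrsf9 without 1 h arrays 2 and 3, 5 h arrays 1, 2 and 3, 15 h arrays 1 and 2 and 25 h arrays 1, 2 and 3 (up to 0.253) and Bub1 without 5 h array 2, 15 h arrays 1 and 2 and 25 h arrays 1 and 3 (up to 0.175). Tnfrsf9 also lost it after median centring (0.0584), with no filter (0.0692) and with no intensity trend (0.0618; range over 25 alternatives 0.00981 to 0.328). The count was 30 without 5 h array 2, 13 without 15 h array 1 or 15 h array 2, and 19 without 25 h array 3, and it was 0 by limma on the 6 arrays of these times (636 at an unadjusted p under 0.05). Without all arrays numbered 1, left out after the data were seen, it was 0 (317 at an unadjusted p under 0.05), or 60 with the block, and 7 of 7 of the largest changes lost their call (0.18 to 0.676), or 2 with the block.

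A pair of genes was carried through every comparison because the study group is known to have followed them up from these arrays, so neither is independent evidence. Mfap5, which encodes the microfibril protein MAGP-2, gave a mean signal of 389 ± 282 at 1 h, 328 ± 155 at 5 h, 259 ± 160 at 15 h and 364 ± 198 at 25 h. None of its changes passed the test against 1 h (at 5 h, log2 change -0.07 ± 0.69, adjusted p = 0.98; at 15 h, log2 change -0.62 ± 0.69, adjusted p = 0.558; at 25 h, log2 change -0.03 ± 0.69, adjusted p = 0.975), from 5 to 15 h (log2 change -0.55 ± 0.69, adjusted p = 0.631) or from 15 to 25 h (log2 change 0.58 ± 0.69, adjusted p = 0.933). Lum, the collagen-binding proteoglycan lumican, gave signals of 35.2 ± 12.3, 35.2 ± 3.39, 67.2 ± 5.38 and 123 ± 48.9 at the 4 times, below the brightness filter. In a fit without that filter, chosen for Lum after its signals were seen, it was 3.40-fold higher at 25 h than at 1 h (log2 change 1.77 ± 0.39, adjusted p = 0.00573), or 2.05-fold with the offset (adjusted p = 0.00401, range over 17 alternatives 0.00265 to 0.0318), and its other changes did not pass (adjusted p = 0.987 at 5 h and 0.129 at 15 h against 1 h, 0.178 for 15 against 5 h and 0.727 for 25 against 15 h).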

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

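The first pair was picked by the planned contrast of 15 with 5 h, so its p is no new test. High 5 h values by chance would give its rise and fall. The count over probe sets without a single gene symbol was chosen after the other results were seen. The unfolded protein response list had median log2 changes against 1 h of 0.47 at 5 h and 0.10 at 15 h. The 15 minus 5 h change had a median of -0.51 over 23 genes (adjusted p = 2.26e-06, or 0.241 with an estimated correlation). It was negative within 3 of 3 replicate numbers. The amino acid response list had medians of 0.39 at 5 h and -0.26 at 15 h. Its difference was -0.50 over 20 genes (adjusted p = 3.8e-05, or 0.241 with an estimated correlation), negative within 3 of 3 numbers. Among 962 probe sets above the brightness filter that carry no gene symbol or several, and so entered no comparison, 280 changed between 25 and 1 h in limma over every probe set, 127 of them higher; there are no control samples against which to set this count, and 11, 177, 103 and 0 such probe sets changed at 5 and 15 h against 1 h, 15 against 5 h and 25 against 15 h.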

How the results depend on the processing

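The fits without all arrays numbered 1 or 3, their combinations with the replicate block, the block with an estimated correlation, and the fits of Lum were chosen after the results had been seen; the other alternatives were planned. Of 348 calls of named genes, 348 were kept with the block, 337 with quantile normalization, 318 with median centring, 322 with no filter, 284 of 285 with the stricter filter, 343 with the offset, 333 with averaged probe sets, 332 with no intensity trend and 299 on the 6 arrays alone, with 152 without the arrays numbered 1 and 298 without those numbered 3, and leaving out 1 array kept 3727 and lost 449 over 12 fits. Of 46 called lists, 45 were kept with the block (hypoxia and glycolysis for 25 against 15 h was lost), and the block ended no other call of a gene or, with the preset correlation, of a list; the lists it added are named there. Quantile normalization kept 39, median centring 41, no filter 40, the stricter filter 43, the offset 44, averaged probe sets 43, and the 6 arrays and no trend 46 each; of these losses, 25 against 1 h lost inflammatory genes only with the stricter filter (0.0586), and without the filter the pericyte list's median there was 0.24. Every called list kept the sign of its median under quantile normalization and median centring; of 114 medians of lists not called, quantile normalization turned the sign of 4 and centring that of 22 (2, 5, 5, 7 and 3 for 5, 15 and 25 h against 1 h, 15 against 5 h and 25 against 15 h), all with sizes of at most 0.19. An estimated correlation called 2, 2, 0, 0 and 0 lists for 5, 15 and 25 h against 1 h, 15 against 5 h and 25 against 15 h (7, 3 and 6 at an unadjusted p under 0.05 where it called 0), and with the block 0 in each (2, 5, 9, 7 and 7). The replicate block raised the counts of changed genes to 573, 2969, 3778, 2415 and 314 for 5, 15 and 25 h against 1 h, 15 against 5 h and 25 against 15 h, and the F test's to 4069. Without the arrays numbered 1 the counts were 3, 470, 1559, 3 and 0, with 1035 for the F test, and with the block they were 152, 1937, 2818, 1339, 60 and 2789; the cause was not tested. Without those numbered 3 they were 1148 for 15 against 1 h and 601 for 15 against 5 h, and with the block 397 for 5 against 1 h, 1622 for 15 against 5 h and 244 for 25 against 15 h. The 6 arrays alone, with fewer degrees of freedom, gave 27 for 5 against 1 h and 0 for 25 against 15 h (636 at an unadjusted p under 0.05). Leaving out 1 array gave 34 to 134, 1054 to 1838, 2112 to 2759, 470 to 1153 and 13 to 71 genes, 2137 to 2472 for the F test, and 5 to 11, 9 to 12, 11 to 12, 9 to 12 and 6 to 8 lists; the 11 lists at 5 h came without 5 h array 1. Mfap5 changed sign without 1 array in each comparison, with log2 changes of -0.62 to 0.49, -1.17 to 0.12, -0.59 to 0.57, -0.93 to 0.19 and -0.16 to 1.19, and without the arrays numbered 3, with or without the block, at 0.0147 for 25 against 1 h and 0.0267 for 15 against 5 h; the cause was not tested. Lum ran from -0.12 to 0.32 at 5 h, 0.82 to 1.25 at 15 h and 1.52 to 2.15 at 25 h against 1 h, 0.85 to 0.99 for 15 against 5 h and 0.54 to 1.17 for 25 against 15 h. Testing every probe set gave no list values and the 6 arrays no F test. Signals under 44.9 limit the fold changes of dim genes such as Hp (76.2-fold, 10.5 with the offset) and Rrp12 (34.3-fold, 5.84 with it).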

Other observations

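The tests of RNA quality, replicate numbers, marker levels and time course position given here were chosen after the results they bear on had been seen, and the scaling test and the splits of the samples were planned. Several lists not yet described had members that moved in both directions by 25 h. Of 16 p53 targets 2 rose and 3 fell by both counts (median log2 change 0.05, mean -0.10, test downward, adjusted p = 0.564): Cdkn1a fell 7.10-fold (1902 ± 1214 to 220.2 ± 10.7, adjusted p = 0.000637) and the p53 antagonist Mdm2 2.03-fold (adjusted p = 0.00102), while the sestrin Sesn1 rose 2.15-fold (adjusted p = 0.00141). Of 18 hypoxia and glycolysis genes 3 rose and 5 fell, 5 and 5 adjusted over the list alone, or 6 and 5 after quantile normalization (median 0.20, mean 0.04, test downward, adjusted p = 0.948); the mitophagy receptor Bnip3 rose 3.01-fold (377 ± 20.4 to 1167 ± 319.9, adjusted p = 0.000687) and hexokinase, Hk2, fell 2.30-fold (adjusted p = 0.000806). Of 18 NRF2 targets 7 rose and 3 fell, or 9 and 4 adjusted over the list alone (median 0.40, adjusted p = 0.564), with the mitochondrial superoxide dismutase Sod2 up 2.51-fold (adjusted p = 0.00135) and thioredoxin reductase, Txnrd1, down 2.20-fold (adjusted p = 0.000136). TGF-beta and BMP targets rose in 5 of 19 cases and fell in 2 by both counts, or 3 and 4 after median centring (median 0.20, adjusted p = 0.833), the pseudoreceptor Bambi upward by 3.38-fold (adjusted p = 0.00161). The unfolded protein response, up at 5 h, had 1 of 23 genes higher and 5 lower by both counts (median 0.13, mean -0.08, test downward, adjusted p = 0.624). Folds moved by over 1.5 times to 11.4 for Cdkn1a without 1 h array 2.

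Among markers of other cell types, Cd14, a lipopolysaccharide co-receptor, rose 7.26-fold (969 ± 57.5 to 7206 ± 2083; log2 change 2.86 ± 0.19, SE; adjusted p = 4.07e-06) by 25 h and the tetraspanin Cd53 11.8-fold (adjusted p = 0.000681), whereas the macrophage receptor Csf1r fell 2.97-fold (adjusted p = 0.0135), so that of 4 tested leukocyte genes 2 rose and 1 fell. Without 1 array, Csf1r without 1 h arrays 1 and 2 (up to 0.0632) missed the threshold, and without the arrays numbered 1 too (0.144, range over 25 alternatives 4.78e-05 to 0.144). Neuronal enolase, Eno2, the 1 tested neuron marker, rose 3.40-fold (adjusted p = 0.00303), and 1 of 3 tested astrocyte markers rose, or 0 after quantile normalization or median centring. Of 2 lymphatic markers 1 rose, Nrp2, 1.89-fold (adjusted p = 0.00179), and of the 11 genes of parietal endoderm, the tissue type behind the gel, 0 passed limma's test at 25 h against 1 h over all genes or adjusted over the list alone (median 0.42, adjusted p = 0.564), with 4 at an unadjusted p under 0.05. At 15 h 1 of the 11 was lower over all genes and 0 adjusted over the list alone (2 at an unadjusted p under 0.05): Lamc1, a laminin chain, fell 1.92-fold (adjusted p = 0.0315). Without 1 array, Lamc1 without 1 h arrays 1 and 3 and 15 h arrays 1, 2 and 3 (up to 0.11) missed the threshold, and with averaged probe sets too (0.567, range over 25 alternatives 0.00112 to 0.567). The 1 tested epithelial marker did not pass in any comparison over all genes, and stood at an unadjusted p under 0.05 by 25 h (log2 change 0.57). Folds that moved by over 1.5 times were 6.37 for Cd53 and 4.61 for Csf1r without 1 h array 3. With the offset the fold was 4.72 for Cd53.

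The fall of the G1/S, mitosis and ribosome biogenesis lists and the rise of the lysosome list by 25 h were weighed against 3 technical explanations. Array scaling is argued against. Under quantile normalization or median centring the 4 list medians kept at least 0.818 of their deposited size (lysosome, 0.87 against 1.06). RNA quality is argued against by 3' to 5' control ratios that differed between 25 and 1 h by at most 0.0754 log2. The largest SD of these ratios within a time was 0.0854. A replicate batch is balanced over time, so list medians going the pooled way in 12 of 12 cases within numbers do not test it. With an estimated correlation the lists' adjusted p of 0.0522 to 0.107 limits how firmly the pattern itself can be stated. Whether the cultures divided more slowly was not measured. Growth to confluence, serum and gel contact, not varied in these samples, and processing by time stay open, as untested.

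Most endothelial markers did not reach the median signal of all arrays on at least 3 of 12 arrays, while most fibroblast markers did (4 of 28 against 11 of 14, 2-sided Fisher's exact p = 7.86e-05). A mesenchymal expression profile of these cultures would give such a difference, but the test sets the brightness of different probe sets side by side, which depends on the probe as well as on the transcript, and so decides nothing. Probe sets that fail in any cell stay open too: of 8 endothelial genes with at least 2 probe sets, 3 had one above the filter, and no endothelial reference sample was analysed here. Whether fibroblast-like cells were present beside endothelial cells or the line itself has this profile was not tested.

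Replicate 3 arrays lay further along the time axis than those numbered 1 and 2. Whether these cultures were ahead in time stays open: the deviation of replicate 3 from the others correlated across genes with the 25 h minus 1 h change of replicates 1 and 2 by r = 0.11 at 5 h and 0.26 at 15 h, but replicate 3 was singled out by its place on that axis, so these values restate the pattern and decide nothing. Mean spike-in signal argues against hybridisation: replicate 3 lay -0.0173 log2 from replicate 2, and replicate 1 was 1.12 above the others. RNA quality is argued against by 3' to 5' ratios within 0.0571 log2 of the others.

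Other groupings of the samples were fitted in the same way. For each comparison the 6 samples can be parted in 10 ways, too few for a share under 0.05, and 1 of 10, the real one, gave the most genes: 122 at 5 h, 1756 at 15 h and 2705 at 25 h against 1 h, 1068 for 15 against 5 h and 57 for 25 against 15 h. The highest other split gave 1, 0, 0, 0 and 0 genes by limma. At an unadjusted p under 0.05 the real splits gave 1017, 2730, 3401, 2319 and 663 genes and the highest others 870, 659, 559, 602 and 870, so that for 25 against 15 h 3 other splits gave more than the real one. Of these 3, 0 part all pairs; among the 4 splits that part all 3 pairs, as the real one does, the highest other gave 0 in each comparison. For the F test, 1 of 100 splits of 12 samples into 4 groups of 3, the real one, reached 2576 genes. The highest other gave 240, but these splits need not part the pairs and decide nothing. Among 100 splits with 1 sample of each number per group, 1, the real one, reached 2576, and the highest other gave 1899. Chance can be excluded at that share. Such splits can follow the time course in part, which points to a structure of the samples.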
